A study of Mus musculus with 52 samples.

How the data were processed

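Single cells from mouse bone marrow were profiled by Smart-seq2, a plate method that makes full-length cDNA from 1 cell per well and carries no molecular identifiers. The labels describe 52 libraries as primed HSCs (haematopoietic stem cells) from C57BL/6 mice of the Cd4-cre;R26Tdtomato genotype, aged 6 to 8 weeks, in which Cre recombinase under Cd4 control can switch on a tdTomato reporter. Per the labels' protocols, marrow was flushed from femora and tibiae and red cells were lysed with ammonium chloride. The sort gate, the number of animals, the plates and the meaning of "primed" are not given in the sources used here. Each library is called here a cell, with the number in its title.

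The authors deposited estimated counts per gene (expected counts, of which 4.23% were not whole numbers) for 28786 Ensembl gene identifiers in 52 cells. Reads were trimmed with Trim Galore 0.5.0 and quantified with Salmon 0.03.1 against GRCm38, per the submitters' processing notes, and the version is printed as those notes give it. The transcript set, the step that summed transcripts to genes, the strand setting and any filter applied before deposit are not given in the sources used here. An estimated count shares reads of near-identical genes among them by a model, so the levels of Hba-a1 and Hba-a2, Hbb-bt and Hbb-bs, H2-K1 and H2-D1, the Ifitm genes and Serpina3g are uncertain in their split. Overlapping and antisense genes are uncertain for the same reason. Symbols and coordinates came from GENCODE release M21, which is on GRCm38, and 27728 of the identifiers (96.3%) had a symbol there. Of all gene entries, 13620 were at 0 in every cell. Xist was the 1 gene of the fixed lists that was not analysed here, and neither tdTomato nor Cre was analysed here.

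The expected counts were rounded to whole numbers, called reads below, and divided by each cell's total to give CPM, the count scaled to the same total in every cell. CPM was not corrected for transcript length, so it compares a gene between cells better than it compares genes. Cells were kept with at least 50000 reads, at least 1000 genes with a read and at most 20% mitochondrial reads. This left 49 cells, and cells 5, 10 and 12 were left out. Kept cells held a median of 2187580 reads, from 85519 to 12446477, and a median of 7041 genes with a read, from 1527 to 9624. Their mitochondrial share had a median of 3.44% (range 0.629% to 6.04%). No doublet caller was run, because 52 sorted wells are too few to simulate doublets from, and doublets are weighed in the closing section.

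All cells carry 1 label and no animal is named, so the data form 1 sample with no replicate. Cells are not replicates, and no p-value or standard error was computed and no groups of cells were tested against each other. An exception to treating cells so is the correlation of Bhlhe41 with total reads, for which limits were drawn by resampling cells. Those limits take cells as replicates and are not printed. Shares of cells carry exact Clopper-Pearson 95% intervals. For 0 of 49 cells the limit printed is 6.12%, from the 3 counts that a count of 0 allows, and the exact interval ends at 7.25%. Either limits the share of cells with a read, not of cells that express the gene. Both cover counting error only, and PCR reads without molecular identifiers are not independent molecules. Values after ± are the standard deviation (SD) over cells.

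Before the data were examined, 24 gene lists (310 entries, 301 distinct genes) were fixed. They cover HSC identity, multipotent progenitors, early lymphoid priming, Notch and T lineage specification, mature T cells, thymus homing, NK and innate lymphoid cells, B lineage, neutrophil and monocyte lineage, megakaryocytes, erythroid cells, mast cells with basophils and eosinophils, dendritic cells and stroma with endothelium. The rest cover genes of other organs as a negative control, DNA replication (G1/S), mitosis (G2/M), quiescence, immediate early response, interferon response, MHC class I, housekeeping and Y-linked genes, and Xist. A gene counted as detected in a cell with at least 1 read, and shares at 10 CPM are given where depth matters. A cell counted as cycling with at least 50% of the G2/M list detected.

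Co-variation of a list was the mean pairwise Spearman correlation of its members over cells, among members with a read in at least 5 cells. It was placed among 10000 random lists matched on mean CPM, and called high where at most 2.5% of random lists lay above. Variability was the residual of the log10 squared coefficient of variation from a lowess curve (fraction 0.3) on log10 mean CPM, over 9158 genes with a mean of at least 5 CPM and a read in at least 10 cells. Cells were clustered by Ward's method on 10 principal components of log2(CPM + 1) over the 1000 most variable genes, with 2 to 6 clusters chosen by mean silhouette and compared with 100 sets in which each gene was permuted over cells. A cluster was called "like" a cell type from the fixed lists alone, lists of the cell cycle and of responses not being counted. The name needed at least 3 list genes higher by at least 1 on the log2 scale than in the other cells. No other cell type list could have more genes in the cluster's top 10. Only genes with a read in at least 50% of the cluster's cells could count as higher.

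Genes named with values followed a rule fixed beforehand. It covers Cd4, Kit, Ly6a, Procr, Slamf1, Hlf, Mecom, Cd34, Flt3, Cd48, Ptprc, Cd3e, Trbc2, Gata3, Tcf7, Notch1, Bcl11b, Runx1, Runx3, Zbtb7b, Il7r, Ccr9, Ighm, Mpo, Vwf and Mki67. It adds the 2 members of each other list found in most cells, the 15 most variable genes, the 10 most abundant non-mitochondrial genes and the 5 leading genes of each cluster. Every other gene given with a value, as an example of its list or as a feature of a single cell, was chosen after its values were seen. A few genes that the rule or the lists include are not reported here by name and are left out of the figures.

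The steps were tested on simulated counts for the same 49 cells and 9158 genes, with 200 genes changed in 18 cells. Of the genes changed 4-fold, 78% fell among the 1000 most variable, as did 100% of those changed 16-fold. The share of unchanged genes there, 9.18%, follows from the fixed size of that set and is no error rate. The 2 simulated clusters were recovered with an adjusted Rand index of 1 when their number was given. The choice of their number by silhouette is not reported for the simulation. Of 40 unchanged lists, 0 passed the co-variation limit. Simulated genes were drawn independently, so this count does not cover real genes that vary together. Alternatives fixed beforehand changed the detection minimum, the depth by thinning every cell to 85519 reads, the cell filter, the share of cells or genes required, the normalization, the correlation, the numbers of variable genes and components, the pseudocount and the clustering method. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scikit-learn 1.9.0, statsmodels 0.14.6 and matplotlib 3.10.9.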

Results

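Transcriptomes of 52 single bone marrow cells, all labelled primed HSCs, were described for the programmes they carried. The labels give 1 group and no control, so the report sets gene lists and cells side by side and compares no conditions. The 49 cells kept held 85519 to 12446477 reads each. With 1 sample and no replicate, every interval covers counting error only.

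Part of the HSC list was found in most cells, while several genes used to mark long-term HSCs were found in few. Of the 28 genes of the HSC list, 13 had a read in at least 50% of the cells (9 at 10 CPM or more), and a list gene was found on average in 48.5% of cells. Kit, the stem cell factor receptor, was found in 48 of 49 cells (98.0%, interval 89.1 to 99.9) at 553 ± 361 CPM (SD over cells). The transcription factors Lmo2 (49 cells, 685 ± 501 CPM), Tal1 (48 cells), Gata2 (47 cells, 368 ± 408 CPM) and Runx1 (39 cells, 82.4 ± 114 CPM) were also widespread, and Kit, Lmo2, Tal1 and Gata2 are used by erythroid progenitors too. At least 50% of the HSC list had a read in 21 cells, which were all 18 of the HSC-like cells described below and 3 of the 30 erythroid-like cells.

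Among genes used to mark or regulate HSCs at the top of the hierarchy, Ly6a, which encodes Sca-1, had a read in 8 cells (16.3%, interval 7.32 to 29.7). Procr, which encodes EPCR, was found in 6 cells (12.2%, 4.63 to 24.8) and Slamf1, which encodes CD150, in 8 cells (16.3%). The HSC transcription factors Hlf and Mecom were found in 17 cells (34.7%, 21.7 to 49.6) and 11 cells (22.4%, 11.8 to 36.6). At 10 CPM or more these shares were 8.16% for Ly6a and Procr, 10.2% for Slamf1, 28.6% for Hlf and 12.2% for Mecom. Of the 10 multipotent progenitor genes, 4 had a read in at least 50% of cells, and 2 reached 10 CPM in as many. Cdk6, a kinase of G1 entry, was found in 48 cells at 848 ± 532 CPM, Cd48 in 30 cells (61.2%) at 57.4 ± 89.8 CPM and Cd34 in 21 cells (42.9%) at 187 ± 372 CPM. Flt3, the receptor of lymphoid-primed progenitors, had a read in 33 cells (67.3%) but reached 10 CPM in 4 (8.16%).

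**Figure D1:**
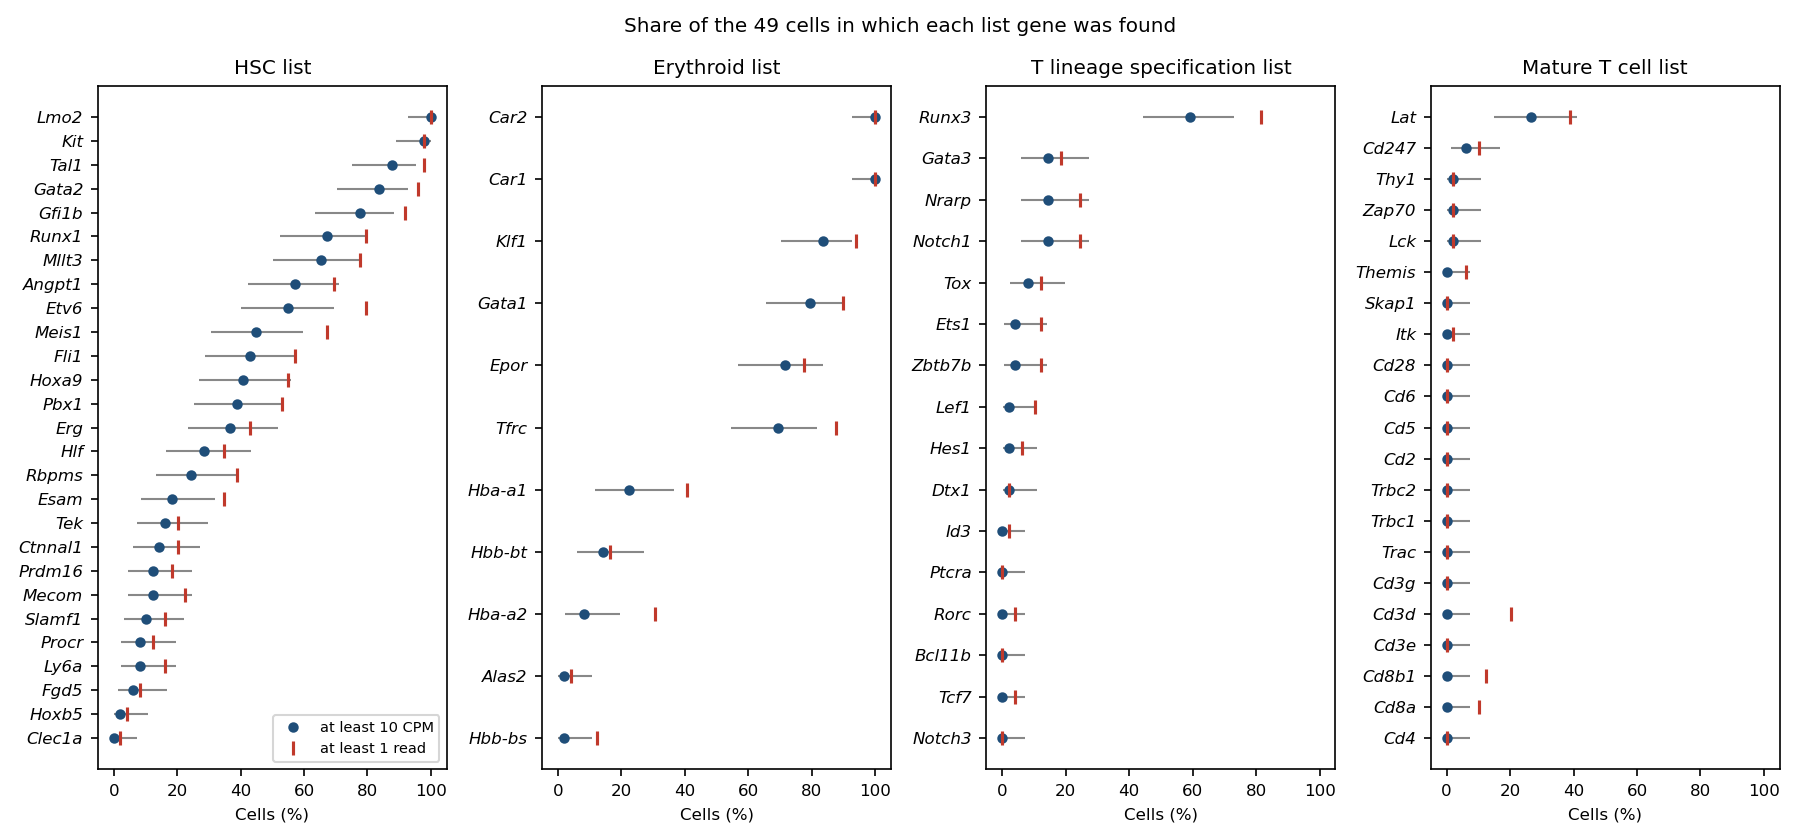
Share of the 49 kept cells (percent, x axis) in which each plotted gene of 4 fixed lists (y axis) was found. Blue points are shares at 10 CPM or more with exact 95% intervals as grey lines, and red ticks are shares with at least 1 read. Lmo2, Car1 and Car2 lie at 100%, Runx3 is the T lineage gene furthest right at 81.6% with a read, and Cd4 lies at 0%.

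T lineage genes were scarce in these cells. Cd4, whose regulatory sequence drives Cre in these mice, had 0 reads in all 52 cells (chromosome 6, 124864692 to 124888221, minus strand), and 0 of 49 kept cells allows a share of cells with a read of up to 6.12%. No read fell on Cd3e, Trbc2, Bcl11b, Il7r or Ccr9 in the kept cells either. Of the 21 mature T cell genes 0 had a read in at least 50% of cells and 11 had none at all. Lat, an adaptor of T cell receptor signalling that other blood cells also use, was the list gene found most often, in 19 cells (38.8%) at 35.4 ± 77.5 CPM.

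Of the 16 genes of T lineage specification, only Runx3 was found in at least 50% of cells, and 3 had no read. Runx3, a transcription factor of CD8 and innate lymphoid cells that is used in other blood cells too, was found in 40 cells (81.6%, interval 68.0 to 91.2) at 67.5 ± 103 CPM, and in 59.2% at 10 CPM or more. Notch1 was found in 12 cells (24.5%) at 25.1 ± 80.2 CPM, Gata3 in 9 (18.4%) at 25.7 ± 82.5 CPM and Zbtb7b, the CD4 lineage factor ThPOK, in 6 (12.2%). Tcf7, an early target of Notch in the thymus, had a read in 2 cells (4.08%) and reached 10 CPM in 0. A T specification gene was found on average in 13.4% of cells and a mature T gene in 5.05%, against 2.55% for the 20 genes of other organs. At 10 CPM or more these averages were 7.78%, 1.85% and 0.612%. In the HSC-like cells described below they were 11.1%, 3.70% and 1.11%, and in the erythroid-like cells 5.625%, 0.794% and 0.333%. The genes of other organs were thus also higher in the HSC-like cells. Lat was the 1 mature T gene with a read in at least 50% of the HSC-like cells.

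Of the 16 early lymphoid genes, 7 had a read in at least 50% of cells and 5 in none, and 4 reached 10 CPM in at least 50%. The widespread ones were led by Bcl11a (49 cells, 189 ± 119 CPM) and Ikzf1 (47 cells, 253 ± 155 CPM), which encode transcription factors that stem cells and other lineages also use. Of the 7 thymus homing and retention genes, 3 were found in at least 50% of cells, among them the integrin gene Itga4 (47 cells, 183 ± 123 CPM) and Selplg, which encodes the P-selectin ligand PSGL-1 (46 cells, 136 ± 144 CPM).

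Erythroid genes were the lineage list found most often, on average in 59.9% of cells. Car1 and Car2, carbonic anhydrases of early erythroid cells, were found in all 49 kept cells at 4414 ± 3551 and 3361 ± 2321 CPM, and Car1 ranged from 10.4 to 11825 CPM. Klf1, the erythroid master regulator, was found in 46 cells (93.9%, interval 83.1 to 98.7) at 632 ± 476 CPM, and Gata1 in 44 cells at 408 ± 302 CPM. The genes of later red cell maturation were low, with Alas2 in 2 cells and the globin gene Hba-a1 in 20 cells at 15.4 ± 61.5 CPM.

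Other lineage lists were found less widely. Dendritic cell genes were found on average in 38.8% of cells, led by Bst2 and Tcf4 (42 cells each), and megakaryocyte genes in 34.5%, led by Cd9 (47 cells, 104 ± 142 CPM) and Vwf. Vwf, the platelet adhesion protein, had a read in 35 cells (71.4%) but reached 10 CPM in 8 (16.3%). B lineage genes averaged 18.5%, and Ebf1 in that list had a read in 40 cells at only 4.73 ± 11.3 CPM, followed by Cd79b (18 cells). The immunoglobulin gene Ighm was found in 10 cells (20.4%). Neutrophil and monocyte genes averaged 11.6%, with Lyz2 in 35 cells, Prtn3 in 24 and Mpo, the granule peroxidase, in 9 (18.4%). NK and innate lymphoid genes averaged 9.69% (Il1rl1 in 31 cells, Nkg7 in 24), stromal and endothelial genes 10.7% (Lepr in 25 cells at 1.42 ± 2.69 CPM, Col1a2 in 8) and mast cell, basophil and eosinophil genes 1.79% (Cpa3 in 4 cells, Fcer1a in 2). Ptprc, which encodes the pan-leukocyte antigen CD45, was found in 43 cells. Reads of Cyp2e1, a liver gene of the negative control list, were found in 13 cells, though in 0 at 10 CPM or more, and Insl3 of that list was found in 5 cells, all HSC-like, and reached 10 CPM in 4 of them. Shares at either minimum can therefore include some background. At 10 CPM or more the averages were 50.9% for erythroid, 29.3% for dendritic, 21.9% for megakaryocyte, 7.63% for neutrophil and monocyte, 7.31% for B lineage, 5.74% for NK and innate lymphoid, 3.63% for stromal and endothelial and 0.765% for mast cell, basophil and eosinophil genes.

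The cells separated into 3 clusters, 1 of them a single cell, with a mean silhouette of 0.375 against at most 0.112 in the 100 permuted sets. With 2 clusters the mean silhouette was 0.369, so the choice of 3 was close. The permuted sets speak for some structure and not for the number of clusters. The largest held 30 cells (61.2%, interval 46.2 to 74.8) and was erythroid-like, because 7 of the 12 erythroid genes, among them Klf1, Gata1, Epor, Car1, Car2 and Tfrc, were higher there. The next held 18 cells (36.7%, 23.4 to 51.7) and was HSC-like, with 15 of the 28 HSC genes higher, among them Meis1, Hlf, Mecom and Erg, together with 4 multipotent progenitor genes that include Cd34 and 5 of the 12 megakaryocyte genes (Pf4, Itga2b, Gp9, Selp and Cd9). Further HSC genes were higher there too but had reads in too few HSC-like cells to count. Among them were Ly6a (by 1.87 on the log2 scale, reads in 6 of 18 cells) and Slamf1 (by 1.34, 4 of 18). The mitosis genes Top2a and Mki67 were also in the top 10 of the erythroid-like cells. Cell 34 stood alone and met the rule for more than 1 name, with 6 of the 19 neutrophil and monocyte genes and 4 of the 9 dendritic genes higher, and 1 of each, Lyz2 and Cd74, in its top 10. It is called neutrophil/monocyte-like by the larger count, but it had reads of 36.8% of that list and of 55.6% of the dendritic list. The leading genes were Tspo2, Aqp1, Trib2, Cyth3 and Klf1 in the erythroid-like cells, Serpina3g, Ctla2a, Pkm, Tmem176b and Meis1 in the HSC-like cells, and Lyz2, Ear2, Tyrobp, Ctss and Pld4 in cell 34. Median depth was 2993790 reads in the erythroid-like and 1192450 reads in the HSC-like cells.

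Because these genes helped to define the clusters, their levels describe the clusters and are no separate finding. With all genes of the fixed lists left out of the clustering, an alternative added after the data were seen, 1 of the 49 cells, cell 13, changed its class. That run gave 6 clusters, each given the class most of its cells came from. Cells 9 and 34 each stood alone there, so by this rule they could not change class. The run is no independent check, because genes outside the lists that vary with them could stay in. Cd34 reached 10 CPM in 14 of the 18 HSC-like cells (508 ± 467 CPM) and in 0 of the 30 erythroid-like cells. Kit was present in both, at 691 ± 333 CPM in HSC-like and 489 ± 352 CPM in erythroid-like cells. Car1 averaged 1558 ± 2408 CPM in HSC-like and 6273 ± 2858 CPM in erythroid-like cells, while Car2 was closer, at 2603 ± 1870 and 3926 ± 2409 CPM. Cells 2, 3, 13 and 38, the HSC-like cells that k-means placed with the erythroid-like cells, a split made after the data were seen, held 81.2% of the summed Car1 of the HSC-like cells. Car1 averaged 5692 ± 1437 CPM in these 4 and 376 ± 585 CPM in the other 14, and Cd34 23.1 ± 45.3 and 646.6 ± 437 CPM. Of the top-of-hierarchy genes, Ly6a, Procr and Slamf1 each reached 10 CPM in 4 of the 18 HSC-like cells, Hlf in 13 and Mecom in 6. Notch1 reached 10 CPM in 7 of the 18 HSC-like cells and in 0 of the 30 erythroid-like cells, Gata3 in 4 and 3, and Runx3 in 9 and 20.

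Some cells fitted their cluster poorly. Cell 9, the shallowest kept cell with 85519 reads and 1527 genes, was placed with the erythroid-like cells and had 7004 CPM of Car1, but had 0 reads of Gata1 and 1 read of Kit. It also had the highest levels of the B lineage genes Igkc (3531 CPM), Cd79a (2304 CPM), Ighm (1602 CPM) and Pax5 (152 CPM), a feature picked out after its values were seen. Cell 34 had 39230 CPM of Lyz2 and 0 reads of Kit. Cell 13 resembled erythroid-like cell 6 closely (correlation of log2 values 0.965 against a median of 0.667 over pairs), and 90 of the 107 rare genes of cell 25 (84.1%) reached 10 CPM in cell 23. Without cells 9, 13, 23 and 34, the partition held 2 clusters, of 28 and 17 cells, and 0 of the remaining 45 cells changed class.

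**Figure D2:**
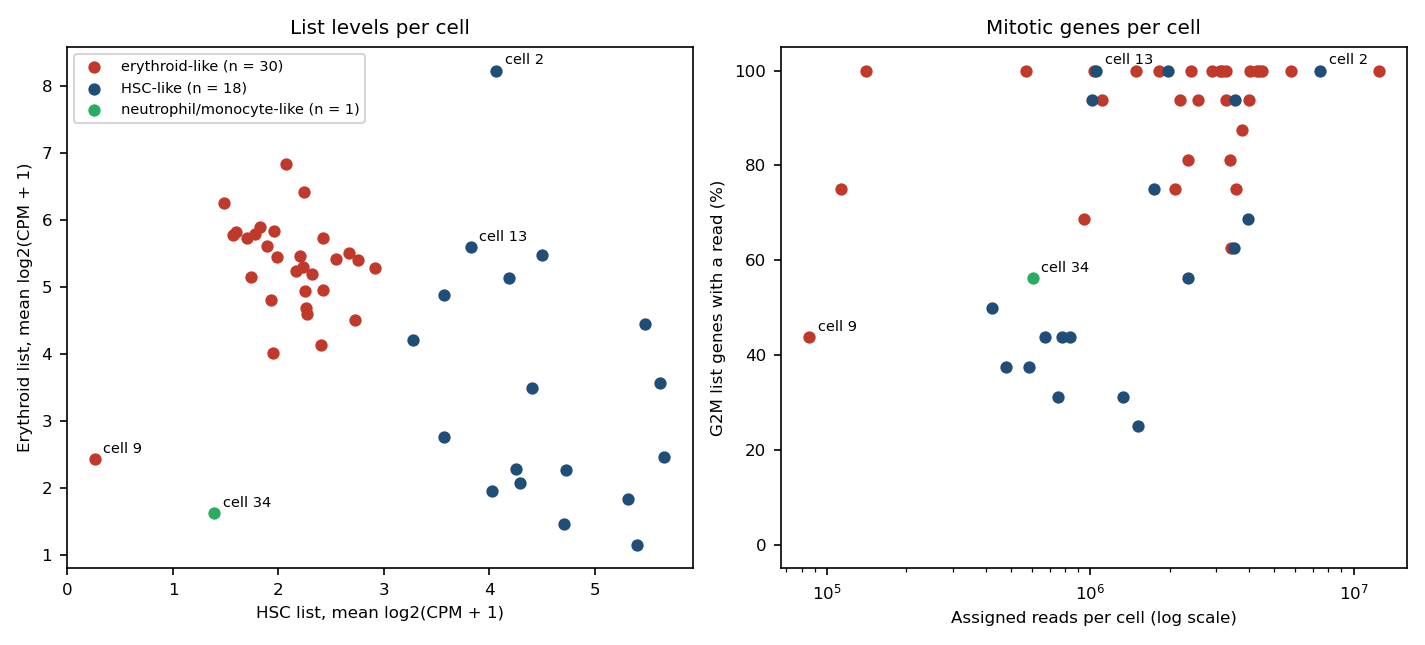
Left, mean log2(CPM + 1) of the HSC list (x axis) against that of the erythroid list (y axis), 1 point per kept cell, coloured by cluster. Right, assigned reads per cell (log scale) against the percent of the 16 G2/M genes with a read. The 30 erythroid-like cells lie at low HSC values, and cell 9 is low in both lists. Cell 2 has the highest erythroid value of the HSC-like cells, and others, such as cells 7, 13 and 38, are high in both lists too.

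**Figure D3:**
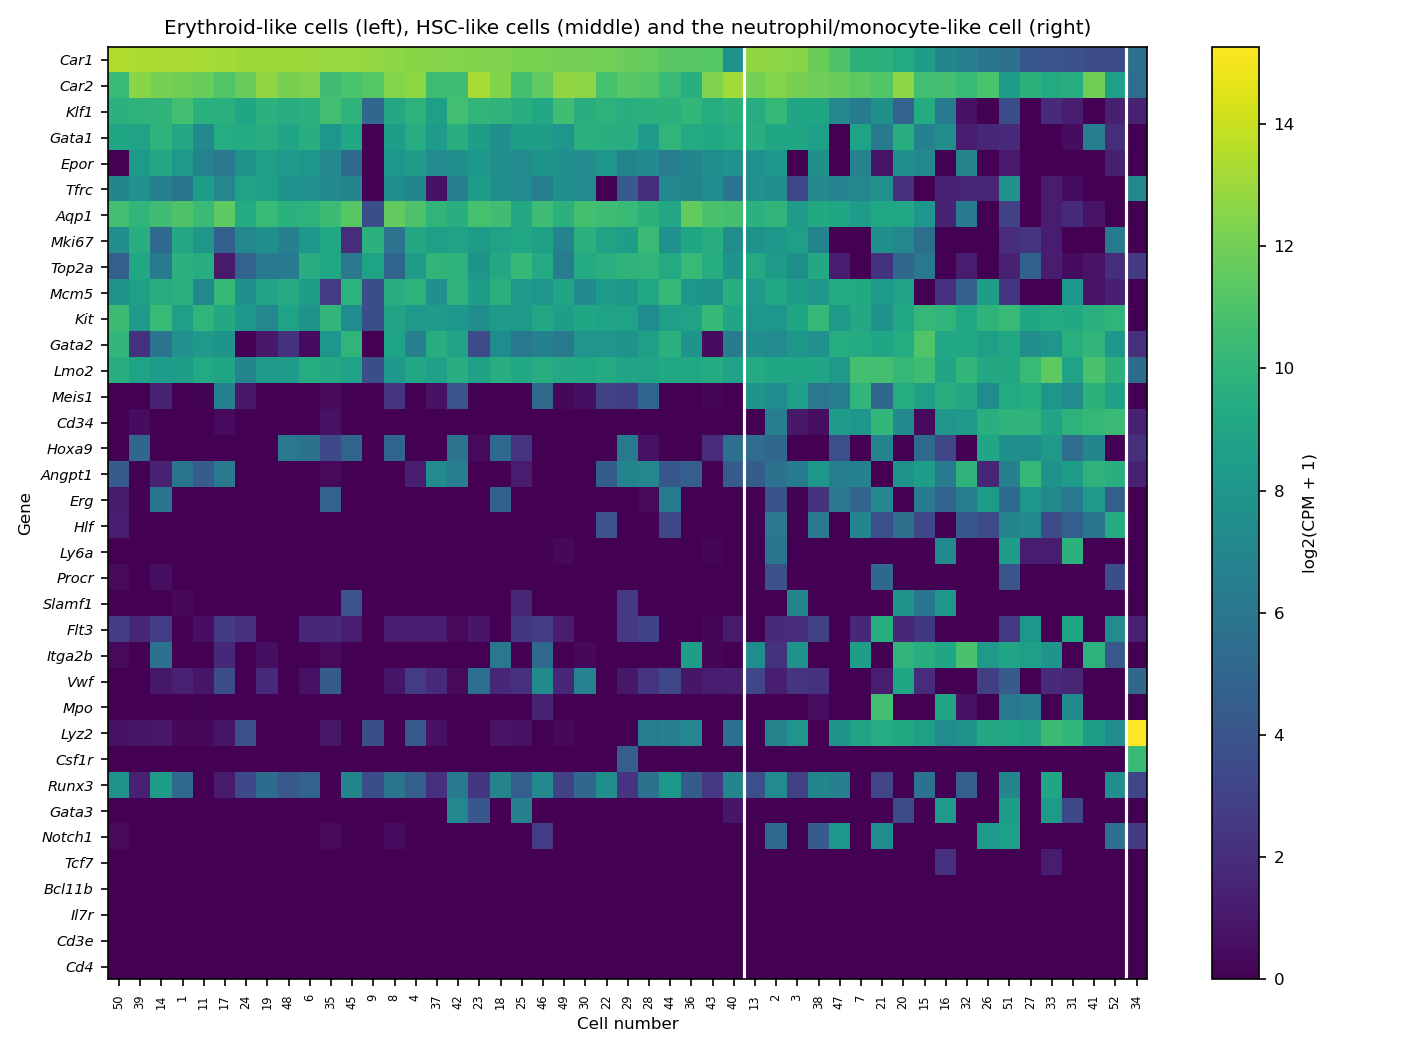
log2(CPM + 1) of selected genes (y axis) in each kept cell (x axis, cell number), ordered by cluster and then by falling Car1 level. The white lines part the 30 erythroid-like cells, the 18 HSC-like cells and cell 34. Car1 and Car2 have reads in every cell, and Il7r, Cd3e, Bcl11b and Cd4 in none.

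Genes of proliferation were widespread. At least 50% of the 16 G2/M genes had a read in 40 of 49 cells (81.6%, interval 68.0 to 91.2), comprising 29 of the 30 erythroid-like cells, 10 of the 18 HSC-like cells and cell 34. At 10 CPM or more 31 cells met this mark, 26 of them erythroid-like and 5 HSC-like, and 4 of those 5 were cells 2, 3, 13 and 38. Mki67, the proliferation marker Ki-67, was found in 41 cells and averaged 402 ± 307 CPM in erythroid-like and 82.04 ± 119 CPM in HSC-like cells, or 33.4 ± 63.7 CPM in the 14 without these 4. Top2a (46 cells) and Ccnb2 (45 cells) led the list. Every kept cell had at least 50% of the 18 G1/S genes with a read, and at 10 CPM or more 42 did, comprising all 30 erythroid-like and 12 of the 18 HSC-like cells. The replication helicase genes Mcm6 and Mcm7 were found in all 49 at 734 ± 531 and 511 ± 366 CPM. The clusters differ in depth, and with every cell thinned to 85519 reads 33 cells met the G2/M mark.

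Across cells, 10 of the 20 lists that could be scored varied together more than nearly all random lists did. The strongest were the G2/M list (mean correlation 0.599 against a random median of 0.0640), the G1/S list (0.511) and the immediate early list (0.361). MHC class I (0.290), erythroid (0.277), HSC (0.215), megakaryocyte (0.205), multipotent progenitor (0.180), neutrophil and monocyte (0.160) and interferon genes (0.116) followed. The 8 scorable T specification genes had a mean correlation of 0.0355, at percentile 45.2 of the random lists, and 5 mature T genes reached 0.0933 at percentile 85.02. The other lists below the limit were B lineage (percentile 91.6), stroma and endothelium (84.97), early lymphoid (80.2), dendritic (71.3), quiescence (64.6), housekeeping (56.8), thymus homing (33.2) and NK and innate lymphoid genes (16.2). The calls of 5 lists depended on the setting. By Pearson correlation of log2 values the MHC class I (percentile 79.7), immediate early (96.25, at 0.316 against a random median of 0.147) and interferon lists (97.03) fell below the limit. With all 52 cells the interferon (93.4) and the neutrophil and monocyte lists (95.99) did. B lineage passed in these settings and on thinned cells, and lay at percentile 47.1 without cells 9, 13, 23 and 34.

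The most variable genes for their mean level peaked in 2 cells. Cell 34 had the highest level of 8 of the 15, which were Lyz2, Cst3, Tyrobp, Fcer1g, Xkrx, Lsp1, H2-Ab1 and Cd74, several of them myeloid or antigen presentation genes. Cst3, for example, reached 13997 CPM there and 971 CPM in the next cell. Cell 9 had the highest level of the other 7, which were Bhlhe41, Ibtk, Chtf18, Pole, Slu7, Ralgps2 and Trafd1. Without cells 9, 13, 23 and 34, an alternative added after the data were seen, 1 of these 15 remained, Bhlhe41. The list then also held Serpina3g, Car1, the immediate early genes Jun, Nr4a1 and Zfp36, and the interferon-inducible genes Tgtp1, Tgtp2 and Oas2.

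The most abundant genes outside the mitochondria were mostly genes of translation and protein folding. Eef1a1 averaged 10632 ± 2042 CPM, Rpsa 5518 ± 1610, Rplp0 4349 ± 1195 and Eef2 3713 ± 1041 CPM. The chaperones Hspa8 and Hsp90ab1 averaged 3831 ± 1541 and 3818 ± 982 CPM, and Car1 belonged to the same group of 10. Bhlhe41, a circadian transcription factor gene, averaged 10516 ± 21957 CPM with a median of 4683 CPM, and its CPM was lower in deeper cells (Spearman -0.43 over the erythroid-like and -0.69 over the HSC-like cells, given without a test). ENSMUSG00000082697, an identifier with no symbol in the annotation used, averaged 6866 ± 3297 CPM. Of the housekeeping list, Actb and Gapdh were found in all 49 cells at 2963 ± 833 and 1703 ± 590 CPM.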

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

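The tests of lysed cells, of clustering on thinned cells, of the pair of cells 6 and 13 and of the share of Bhlhe41 at different depths were chosen only after the result was seen, and so was the further matching on transcript length. The design has 1 group, so no biological explanation was tested for any pattern below.

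Signal appeared in the 3 cells that the cell filter left out, which entered only the alternatives with all 52 cells. Car1 stood at 391 CPM (120 reads) in cell 5, 403 CPM (16 reads) in cell 10 and 4994 CPM (162 reads) in cell 12. The identifier with no symbol, ENSMUSG00000082697, averaged 6866 CPM and is in no list.

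Erythroid genes filled most cells of a population labelled HSCs. RNA from lysed red cells or erythroblasts would bring globin, the most abundant transcript of those cells, above Car1, but in the 30 erythroid-like cells the 4 adult globin genes summed to 10.8 ± 23.2 CPM against 6273 ± 2858 CPM of Car1. Deeper sequencing of these cells was argued against by thinning all cells to 1 depth, which moved 6.12% of cells between classes. The thinned run gave 6 clusters, the largest of 32 cells, and each cluster took the class of most of its cells. A cell alone in its cluster, as cells 9 and 34 were there, could not count as moved. Wells with an HSC-like and an erythroid-like cell each were argued against as the general cause, since 9 of the 15 HSC and progenitor genes found in most HSC-like cells reached 10 CPM in under 50% of the erythroid-like cells, with Cd34 in 0 of 30. Early erythroid progenitors inside the sort gate may be a source, and neither the gate nor a mislabelled plate was tested.

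Cells 6 and 13 were nearly alike, with a correlation of log2 values of 0.965 against 0.871 for the next pair and a median of 0.667. Of the 73 rare genes of cell 6 (at 50 CPM or more there and above 10 CPM in at most 10 other cells, a limit relaxed after a stricter one left too few genes), 95.9% reached 10 CPM in cell 13. Among the other pairs the highest share was 84.1%, for genes of cell 25 in cell 23, then 46.97% for genes of cell 6 in cell 2 and 46.9% for those in cell 38, with a median of 14.5%. In the reverse direction, 57.8% of the 90 rare genes of cell 13 reached 10 CPM in cell 6. Of the 92 rare genes of cell 23, 19.6% did in cell 25, and cells 23 and 25 had a correlation of 0.867. Library 13 may thus hold material of library 6, and library 23 material of library 25, for which no further test was run. Deposit of the same library under both numbers was argued against, because 90 genes at 50 CPM or more in cell 13 had no read in cell 6, among them Meis1 at 242 CPM. Carry-over of cDNA, shared indices and wells with an added cell stay open. The codes in the titles of cells 6 and 13 both start with F and are consecutive, as codes of other cells are too. Those of cells 23 and 25 are not consecutive, and what the codes mean is not given.

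Bhlhe41 ranked among the most abundant genes, reached 142986 CPM in cell 9, and its paralogue Bhlhe40 averaged 5.42 CPM. Its share was not the same at any depth, since its CPM fell with total reads over the cells (Spearman -0.64, or -0.60 without cells 9 and 34), within the erythroid-like (-0.43) and HSC-like (-0.69) cells too. Its annotated transcripts hold an A or T run of 39 bases, and 320 other genes with a run of at least 25 had a median correlation of 0.0709 with total reads, against 0.171 in random lists matched on mean CPM, of which 0 of 10000 lay as low, nor did any of those matched on length too. Of these genes 16.3% had a correlation of -0.3 or lower, against 0.799% of genes with no such run. The median over the 320 genes was positive, so most of them took no larger share in shallower cells. The run test passed only relative to the random lists. Reads of primer or poly-A sequence placed on long A or T runs are a candidate source for Bhlhe41. The run test favours it only in this relative sense and without showing where reads fall. A real change of Bhlhe41 with cell RNA content stays open.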

How the results depend on the processing

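The minimum of 50 CPM, the sets without cells 9, 13, 23 and 34 and without cells 2, 3, 13 and 38, and clustering without the fixed lists or on thinned cells were chosen after seeing the data. Of 162 alternative values for 20 results, 146 stayed within limits and 16 moved. The limits are a factor of 1.5 for counts and 1 SD over cells for mean shares, which is wide for low shares. Inside it, at 10 CPM, B lineage fell from 18.5% to 7.31%, T specification from 13.4% to 7.78%, mature T from 5.05% to 1.85% and the negative control from 2.55% to 0.612%. Cd4 stayed at 0 of the cells under every setting run, which its 0 reads in all 52 cells fixed in advance. Its values count among the 146 all the same. The co-variation count lay between 8 and 11 lists, with B lineage, MHC class I, immediate early, interferon, and neutrophil and monocyte genes changing side in at least 1 setting. At 50 CPM, HSC genes in at least 50% of cells numbered 5 and T specification genes 0, mean shares of cells were 30.03% (HSC), 4.59% (T specification), 3.70% (NK and innate lymphoid), 4.59% (B lineage), 14.5% (megakaryocyte) and 19.05% (dendritic), and 25 cells counted as cycling. A stricter detection minimum lowers such values by its construction. Asking for 75% of cells left 8 HSC genes, and asking for 25% gave 1 mature T gene. The number of clusters was 6 by k-means, 6 with the fixed lists left out and 6 on thinned cells, and the cause was not tested. In these settings 4 cells (2, 3, 13 and 38), 1 cell (13) and 3 cells (2, 13 and 38) changed class, with each cluster given the class most of its cells came from. Cells 9 and 34 each stood alone in these settings, and a cell alone in its cluster cannot change class by this rule. Cell 9 also stood alone with 500 variable genes. Of the 15 most variable genes, 7 remained with all 52 cells and 1 without cells 9, 13, 23 and 34. In the main setting cell 34 had the highest level of 8 of the 15 and cell 9 of 7, and the part of each cell in these changes was not tested. Depth limits low genes, because 1 read in the shallowest kept cell is worth 11.7 CPM. No paired analysis was possible because the labels give 1 group.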

Other observations

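No test was run in this part, and the examples were picked after the data were seen. Genes of the early response to stimulation or tissue handling were found in many cells. Of the 13 immediate early genes, 10 had a read in at least 50% of cells (10 in erythroid-like and 9 in HSC-like cells) and 7 reached 10 CPM in as many (7 and 9), led by Ier2 (49 cells) and Fos (48 cells, 948 ± 1266 CPM). Ier2 averaged 1151 ± 1057 CPM in HSC-like and 288 ± 303 CPM in erythroid-like cells, and Nr4a1, an orphan nuclear receptor gene, reached 10 CPM in 16 of 18 and 2 of 30. The heat shock gene Hspa1a of that list had no read. Of the 12 quiescence genes, 7 had a read in at least 50% of cells and 3 reached 10 CPM in as many. The values of Txnip (517 ± 384 against 239 ± 281 CPM) and Foxo3 (155 ± 149 against 48.8 ± 49.6 CPM) are means in HSC-like against erythroid-like cells.

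Antigen presentation and interferon genes were also present. All 9 MHC class I genes had a read in at least 50% of cells (8 at 10 CPM or more), and H2-K1 averaged 3370 ± 1615 CPM in HSC-like and 1438 ± 754 CPM in erythroid-like cells, with B2m at 1835 ± 655 and 1135 ± 296 CPM. Of the 14 interferon genes, 5 had a read in at least 50% of cells (4 at 10 CPM or more). Ifitm3 reached 10 CPM in 18 of 18 HSC-like and 24 of 30 erythroid-like cells (601 ± 333 and 116 ± 133 CPM), while Ly6e was closer between them (686 ± 428 and 505 ± 385 CPM). The 4 Y-linked genes had no read in any kept cell.

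Within the HSC-like cells, genes of other lineages were found. Of the 19 neutrophil and monocyte genes, 2 reached 10 CPM in at least 50% of them and 8 had no read, with a mean share of 12.3% at 10 CPM. Lyz2 reached 10 CPM in 16 of 18 (439 ± 367 CPM) and Prtn3 in 13, against 7 and 6 of the 30 erythroid-like cells. Of the 12 megakaryocyte genes, all had a read in some HSC-like cell, 7 had a read in at least 50% of them and 2 reached 10 CPM in as many, with a mean share of 35.2% at 10 CPM. At least 50% of that list had a read in 10 of 18 HSC-like and 0 of 30 erythroid-like cells. Itga2b, the platelet integrin gene, reached 10 CPM in 13 of 18 and in 4 of 30. Mpo peaked in cell 21 at 1685 CPM and Gata3 in cell 51 at 382 CPM. Cell 2, among the deepest with 7481542 reads and the most genes (9624), combined Car1 at 6366 CPM and Klf1 at 1160 CPM with Meis1 at 172 CPM, Cd34 at 91.0 CPM and Ly6a at 61.9 CPM. Of the index codes in the titles, whose meaning is not given in the sources used here, those starting with F named 2 erythroid-like and 2 HSC-like cells, R 1 erythroid-like cell, and Y 27, 16 and the cell 34.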
